A study of Homo sapiens with 6 samples.

How the data were processed

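RNA was measured in 6 libraries from HEK293 cells, 3 from cells carrying the rs16851030 variant and 3 from wild-type cells. Per the labels' protocols, the variant was introduced by CRISPR homology-directed repair, poly(A) RNA was isolated with oligo(dT) beads, and libraries were sequenced as paired ends on an Illumina NovaSeq instrument. The libraries were grouped by the genotype in their labels, which call them biological replicates. Whether the mutant libraries came from 1 edited clone, from separate clones or from a pool is not given in the sources used here.

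The deposited table holds, per the file headers, 1 count column and 1 FPKM column for each library, for 61806 genes with Ensembl identifiers, coordinates and functional terms. Per the submitters' processing notes, the authors used cutadapt, HISAT2 version 2.0.1 and HTSeq on GRCh38 to make the counts. The annotation release and the strandedness of counting are not given in the sources used here. FPKM recomputed from the deposited counts, the gene lengths and the library totals matched the deposited FPKM within 0.011 for 100% of values. Of the gene identifiers, 58254 were found in GENCODE release 29, and 41634 had identical coordinates there. No gene symbol was given for 20417 genes, and these entered the tests by identifier.

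Depth was 16013460 to 20349609 assigned counts per library. In the tested genes the common biological coefficient of variation was 0.0478, a summary over genes of the spread between replicates. Each gene was tested with a spread estimated for it in the fit. No pair of libraries was a duplicate: the chi-square per degree of freedom between libraries of a group was 2.19 at the least.

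The design, the gene lists, the rule for named genes and the alternatives to be tried were written before the data were examined. The design named limma on log2(FPKM + 1) as the main test unless the table also held raw counts, and because it did, the count test became the main test and the limma fit an alternative. Genes with a mean FPKM of at least 1 over the 6 libraries were tested (12550 genes). Counts were scaled by trimmed mean of M-values (TMM, factors of 0.980 to 1.017) and tested with the quasi-likelihood F-test of edgeR 4.0.16, two-sided, with genotype as the single factor. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. A fold change of at least 2 was a second criterion. Log2 fold changes are mutant minus wild type, with a standard error (SE) from the fit, and FPKM values are means with the standard deviation (SD) of 3 libraries. ADORA1 was also tested in the same fit without the expression filter and by an exact permutation test.

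Genes were named by a fixed rule. It took ADORA1, then the 10 largest rises and 10 largest falls among called protein-coding genes whose 3 mutant values did not overlap the 3 wild-type values and whose mean FPKM was at least 5 in the higher group (4521 genes were eligible), and then up to 4 members of each list with the smallest adjusted p. Genes named outside the rule are marked in the text as chosen after their values were seen. A few genes that the rule covers are not reported here.

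The 30 fixed lists held 1014 entries, of which 995 matched the table; the others were older histone names without an identifier, apart from 1 name that pointed to a gene already in its list. They covered adenosine signalling, G protein and cAMP signalling, neighbours of the edited position, immediate early genes, HIF targets, glycolysis, nuclear respiratory chain genes, mitochondrial DNA genes, ribosomal proteins, mitotic genes, replication genes, p53 targets, apoptosis, the unfolded protein response with ATF4 targets, and heat shock. They also covered interferon response, NF-kB, NRF2, cholesterol, extracellular matrix, adhesion, WNT, TGF-beta with BMP, PI3K with AKT and mTOR, MAPK, DNA repair, histones, neuronal markers, renal markers, and markers of other cell types. Each list was tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the 30 lists, and beside it with an estimated correlation and with fry. The setting with an estimated correlation also has far fewer degrees of freedom, which are set by the 6 libraries. Members were counted with p-values adjusted over all genes and over the list alone. Deposited terms with 10 to 500 tested genes were tested by one-sided Fisher tests for higher and lower genes separately. Genes of each chromosome were tested as a set with camera, and medians were taken in windows of 25 neighbouring tested genes.

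The alternatives were other scalings (median of ratios, quantile, TPM), pseudocounts of 0.1 and 0.5, other expression filters, DESeq2 1.42.0, limma without trend, robust limma, array weights, a replicate block, and each library left out in turn. Library totals as the scaling, terms with libraries left out, and the tests without genes of chromosomes 10, 16, 20 and 22 were chosen after seeing the data. The tools were tested on simulated data made from these libraries. The quasi-likelihood test recovered 60% of genes changed 1.25-fold, 90% at 1.5-fold and 98% at 2-fold, and called 0.057% of unchanged genes. DESeq2 recovered 54%, 86% and 96%, and limma 38%, 82% and 98% at the same fold changes. The 1 list raised in the simulation was called, and 0 unchanged lists were. Genes were drawn independently there, so the simulation does not show how often lists of correlated genes are called by mistake. It changed 50 genes at each fold change, far fewer than were called in the data, so its rates need not carry over. Scripts ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.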

Results

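Poly(A) RNA was sequenced from HEK293 cells, a human line derived from embryonic kidney cells that carry adenovirus DNA. The 6 libraries fell into 2 groups of 3: cells into which the rs16851030 variant had been introduced by CRISPR homology-directed repair, and wild-type cells. The variant lies in the 3′ untranslated region of ADORA1, the gene of the adenosine A1 receptor, and the comparison asked which transcripts differ once it is present. Counts assigned to genes totalled 20349609, 16833776 and 16013460 in mutant replicates 1 to 3 and 17938985, 16867853 and 17750198 in wild-type replicates 1 to 3. Between 24858 and 25833 genes had at least 1 count in a library. Across tested genes, log2 CPM values (counts scaled to the library total) correlated at r = 0.9931 to 0.9951 between libraries of a group and at 0.9722 to 0.9791 between libraries of different groups. These are correlations over genes, which are not independent replicates. The first principal component held 74.4% of the variance and separated the 2 groups. The labels call the libraries biological replicates, and whether the edited cells came from 1 clone is not given in the sources used here. The p-values therefore measure the spread between these libraries.

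ADORA1 (ENSG00000163485, GRCh38 chromosome 1, 203090654 to 203167405, plus strand) was expressed at a low level in both groups. Its FPKM was 0.573 ± 0.0709 (SD, n = 3) in the mutant and 0.480 ± 0.0964 (SD, n = 3) in the wild type. The counts behind these values were 48, 46 and 34 in the mutant libraries and 44, 29 and 33 in the wild-type libraries. The difference lay within the spread between replicates, with a log2 fold change of 0.19 (SE 0.24), a 95% interval of -0.49 to 0.87 and an adjusted p of 0.604 in the quasi-likelihood fit without an expression filter (0.413 to 0.903 over the alternatives). In fold terms the interval ran from 0.711 to 1.82, and differences within it are not excluded. It was built on the residual degrees of freedom alone. The test also borrows information from other genes, so the interval is wider than the test implies. A two-sided exact permutation test on log2 FPKM gave p = 0.30, where 3 against 3 libraries cannot give less than 0.1. With a mean FPKM of 0.527, ADORA1 stayed below the expression minimum of the tests over all genes. ADORA2B, the adenosine A2B receptor gene, was the most abundant adenosine receptor transcript, at 13.18, 11.43 and 12.39 FPKM in the mutant libraries and 11.78, 10.35 and 10.87 in the wild-type libraries. Its log2 fold change in the same fit was 0.10 (SE 0.08, adjusted p = 0.467). ADORA2A, which the rule for named genes did not cover, had 3 to 10 counts per library.

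The edited and wild-type cells differed in many transcripts, most of them by a small amount. Of 12550 tested genes, 7284 (58.0%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with 3686 higher and 3598 lower in the mutant. The median absolute log2 fold change of these genes was 0.37, and 5482 of them (75.3%) differed by less than 1.5-fold. A difference of at least 2-fold was found for 546 genes, of which 447 were higher and 99 lower in the mutant. The 3 mutant values lay entirely above or below the 3 wild-type values for 7893 genes (62.9%), against 10% by chance. The split between higher and lower genes differed between settings. Of the called genes, 50.6% were higher in the main test, 56.9% in the same test with library totals as the scaling, 55.7% in limma on log2(FPKM + 1), 47.6% (3277 higher, 3608 lower) in limma after quantile normalization and 62.4% (4191 higher, 2525 lower) in limma on values rescaled to a common total (TPM).

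EGR1, an immediate early transcription factor, had the largest rise among the genes eligible for naming, from 1.14 ± 0.0981 to 23.9 ± 11.6 FPKM (SD, n = 3), a log2 fold change of 4.37 (SE 0.29, adjusted p = 1.07e-09). FOS, another immediate early factor, rose by 4.07 (SE 0.33) from 0.313 ± 0.102 FPKM (SD, n = 3). PTN, which encodes the secreted growth factor pleiotrophin, rose from 0.550 ± 0.0872 to 6.55 ± 0.576 FPKM (log2 fold change 3.53). The other large rises were IL13RA2, an interleukin 13 receptor subunit (3.29), EDIL3, a secreted integrin ligand (3.16), HLA-DRA, an MHC class II chain (3.04), and the histone gene H2BC21 (2.66). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose from 2.71 ± 0.280 to 16.6 ± 0.132 FPKM (SD, n = 3; log2 fold change 2.58, SE 0.08). DDIT4, an inhibitor of mTOR signalling, rose 5.67-fold (6.52 ± 0.516 to 37.9 ± 5.48 FPKM, SD, n = 3), and CCN1, a matricellular protein gene, rose 4.72-fold. Histone and HLA genes have close relatives, so the values of H2BC21 and HLA-DRA are uncertain to the extent that reads were shared.

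Among the genes eligible for naming, the largest falls were led by ALDH1A2, a retinoic acid synthesis enzyme. They included 5 HOX genes, which encode homeodomain factors of axial patterning. ALDH1A2 fell from 12.2 ± 1.84 to 2.51 ± 0.251 FPKM (SD, n = 3), a log2 fold change of -2.31 (SE 0.10, adjusted p = 3.95e-12). HOXB6 fell from 24.9 ± 3.09 to 6.60 ± 1.04 FPKM (log2 fold change -1.96), HOXB5 by 1.56, HOXA6 by 1.54, HOXA5 by 1.49 and HOXA9 by 1.24 on the log2 scale. HOXA5 was the most abundant of them, at 59.8 ± 3.61 FPKM in the wild type and 21.8 ± 1.47 in the mutant (SD, n = 3). MAGEA3, a cancer-testis antigen gene, changed by -2.20, FASTKD5, a mitochondrial RNA processing factor encoded on chromosome 20, by -1.32, and the inducible heat shock gene HSPA1A by -1.24. MT-ND6, encoded on the mitochondrial genome, fell from 613 ± 98.2 to 269 ± 45.8 FPKM (SD, n = 3; log2 fold change -1.23). MAGEA3 and HSPA1A have near-identical copies, MT-ND6 and HOX neighbours overlap other transcripts, and strand use in counting is not given in the sources used here, so these values are uncertain.

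**Figure D1:**
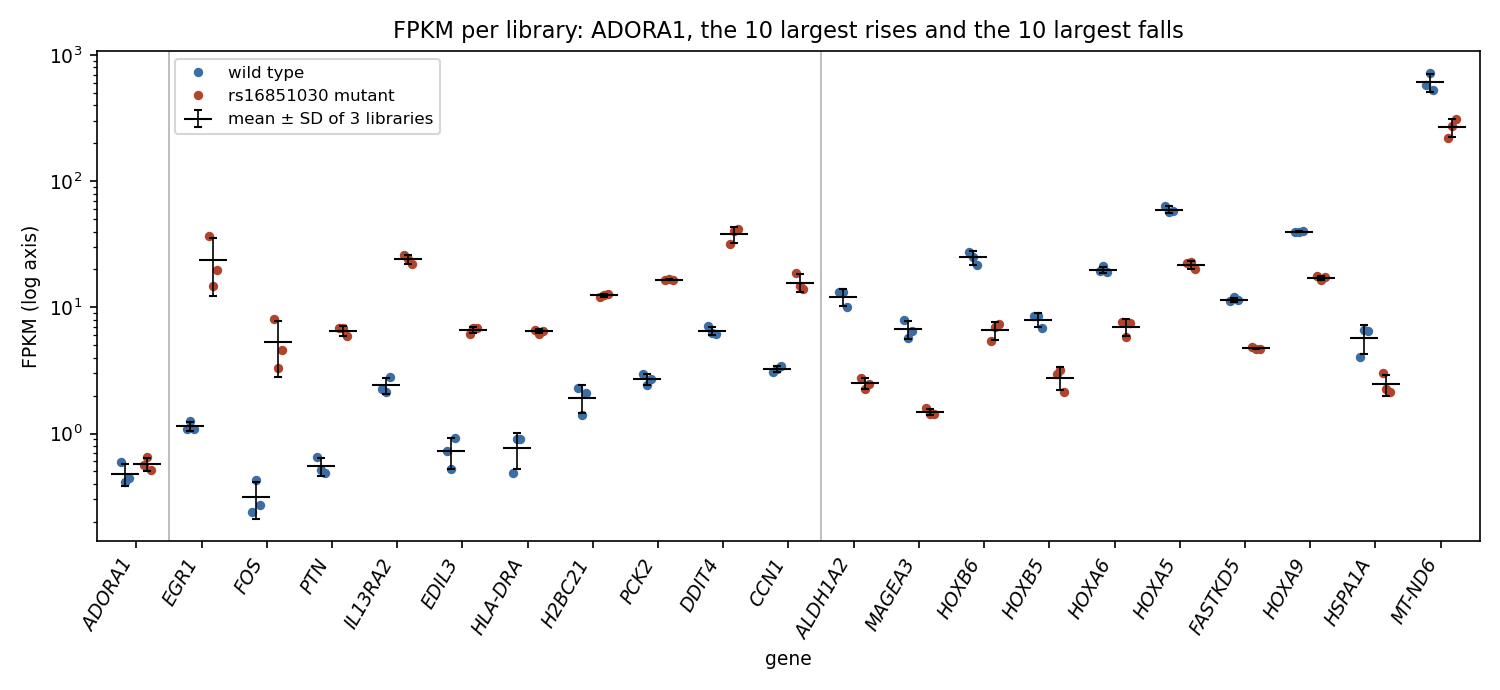
FPKM (log axis) of each library for ADORA1 and, among the genes eligible for naming, the 10 largest rises and the 10 largest falls. Points are the 3 wild-type (blue) and 3 mutant (red) libraries, and black bars are the mean ± SD. The means of ADORA1 were 0.480 and 0.573 FPKM, those of PCK2 were 2.71 and 16.6, and those of ALDH1A2 were 12.2 and 2.51 (wild type, mutant). The rises and falls, unlike ADORA1, were selected for groups that do not overlap.

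Genes of the unfolded protein response and of the ATF4 pathway, which adapts amino acid and redox metabolism to stress, were mostly higher in the mutant. Of 31 tested members, 22 rose, 3 fell and 6 did not pass, with the same counts when adjusted over the list alone. The 3 that fell were CRELD2 (-0.44), PPP1R15A (-0.25) and CALR (-0.25), and DDIT3 (-0.12) did not pass. Several chaperone genes of the endoplasmic reticulum rose little: HSPA5 by 0.25, PDIA4 by 0.22, HYOU1 and PDIA6 by 0.14 and HSP90B1 by 0.12. DNAJB9 rose by 0.53. These genes are named after their values were seen. SLC7A11, the cystine transporter, rose by 2.06 on the log2 scale (SE 0.08; 2.91 ± 0.453 to 12.4 ± 1.00 FPKM, SD, n = 3). HERPUD1, an endoplasmic reticulum stress gene, rose by 1.43, MTHFD2 of mitochondrial folate metabolism by 1.09 and PSAT1 of serine synthesis by 1.03. The list median was 0.30 (camera adjusted p = 1.03e-14 with a preset correlation, and adjusted p = 0.151 with an estimated correlation). Heat shock genes moved the other way: of 16 tested, which include the mitochondrial chaperonin genes HSPD1 and HSPE1 (named after their values were seen), 0 rose, 15 fell and 1 did not pass, again with the same counts when adjusted over the list alone. HSPA8, the constitutive HSP70, fell from 437 ± 11.7 to 207 ± 16.8 FPKM (SD, n = 3), a log2 fold change of -1.11. HSPH1 changed by -1.07, the co-chaperone DNAJA1 by -0.76 and CHORDC1 by -0.61. The list median was -0.59 (adjusted p = 1.43e-12 preset, and adjusted p = 0.0913 with an estimated correlation).

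Among immediate early genes and among HIF targets, more rose than fell in the mutant, the first group led by transcription factors. Of 20 tested immediate early genes, 10 rose, 2 fell and 8 did not pass, with the same counts when adjusted over the list alone. JUN rose from 113 to 280 FPKM (log2 fold change 1.28, SE 0.06) and MYC from 35.3 ± 2.14 to 73.0 ± 2.72 FPKM (SD, n = 3; log2 fold change 1.02, SE 0.05). ATF3, which is also a member of the ATF4 list, rose by 1.60. The list median was 0.37 (adjusted p = 1.65e-06 preset, and adjusted p = 0.287 with an estimated correlation). It was 0.18 with quantile normalization and 0.80 among genes with a mean FPKM of at least 5, and the list was called in both. Of 25 tested HIF targets, 16 rose, 5 fell and 4 did not pass, the same counts as adjusted over the list alone. DDIT4 led them, followed by STC2 (0.98), LOX (0.85) and VEGFA (0.80). The 5 that fell were CITED2, SLC2A1, PFKFB3, KDM3A and BNIP3, named here after their values were seen, of which SLC2A1 encodes the main glucose transporter. The median was 0.32 (adjusted p = 0.00115 preset, and adjusted p = 0.287 with an estimated correlation). DDIT4 and STC2 also respond to ATF4, and STC2 was a member of both lists.

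Extracellular matrix genes rose almost throughout. Of 30 tested collagens, laminins and remodelling enzymes, 29 rose, 0 fell and 1 did not pass, with the same counts when adjusted over the list alone. MMP2, the gelatinase, rose from 2.83 ± 0.0854 to 12.6 ± 0.285 FPKM (SD, n = 3; log2 fold change 2.12; it lies on chromosome 16, as do CDH1 and GNAO1 below), COL12A1 by 3.06, CCN1 by 2.24 and the laminin gene LAMB1 by 1.03. The median was 0.67 (adjusted p = 2.25e-20 preset, and adjusted p = 0.151 with an estimated correlation). Of 27 tested adhesion genes, 18 rose, 5 fell and 4 did not pass, against 19 and 5 adjusted over the list alone. CDH1, the epithelial cadherin, rose by 2.35 from 0.660 ± 0.0436 FPKM (SD, n = 3), ITGA7 by 1.19, ITGA4 by 0.67 and DSG2 by 0.37. The median was 0.36 (adjusted p = 0.00611 preset, and adjusted p = 0.538 with an estimated correlation). Among 15 neuronal genes, 10 rose, 2 fell and 3 did not pass, as also adjusted over the list alone. They included MAPT (0.93) and SYT1 (0.89), whereas the neurofilament gene INA changed by -1.15 (median 0.45, adjusted p = 0.0207 preset, and adjusted p = 0.287 with an estimated correlation). The adhesion and neuronal calls were lost among genes with a mean FPKM of at least 5 (adjusted p = 0.714 and 0.259). Over the alternatives, the adjusted p ran from 1.35e-06 to 0.714 and the median from 0.05 to 0.45 for adhesion, and from 0.00128 to 0.287 and from 0.25 to 0.53 for neuronal genes.

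Of 34 markers of blood, fibroblast, squamous, hepatic and endothelial cells, 3 reached the expression minimum, and the others were not tested. These 3 rose, as also adjusted over the list alone: HLA-DRA (3.04), HBA1 (1.55) and COL1A1 (0.73). Their levels in the mutant were 6.46 ± 0.223, 1.65 ± 0.504 and 4.93 ± 0.192 FPKM (SD, n = 3). The median of 1.55 had an adjusted p of 0.00264 with the preset correlation (adjusted p = 0.287 with an estimated correlation). COL1A1 was also a member of the extracellular matrix list. Because the minimum applies to the mean of both groups, it favours genes that are high in 1 of them, such as HBA1 (0.550 FPKM in the wild type); without a filter the list median was 0.49 (adjusted p = 0.0219). HBA1 has a near-identical copy and its value is uncertain.

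Transcripts of the mitochondrial genome were lower in the mutant. All 13 protein-coding genes of mitochondrial DNA fell, in the test over all genes and adjusted over the list alone. MT-ND5 fell by 1.18, MT-ND2 by 1.02, MT-ND1 by 0.98 and MT-CYB by 0.83 on the log2 scale, and MT-ND2 stood at 1350 ± 140 FPKM in the wild type and 681 ± 45.2 in the mutant (SD, n = 3). The median was -0.71 (adjusted p = 5.74e-09 preset, and adjusted p = 0.366 with an estimated correlation), and -0.44 with quantile normalization. Mitochondrial genes took 1.28 to 1.59% of counts in the mutant libraries and 1.91 to 2.33% in the wild-type libraries. Of 58 nuclear genes of the respiratory chain and ATP synthase, 2 rose (UQCRC2, 0.46, and COX4I1, 0.40), 21 fell and 35 did not pass, against 2 and 18 adjusted over the list alone. ATP5F1C changed by -0.52 and NDUFB9 by -0.35, and the list was not called (median -0.10, adjusted p = 0.0690). It lay close to the threshold and was called in 8 of 18 alternatives, among them those without mutant replicate 2 (adjusted p = 0.00901), without wild-type replicate 1 (0.0424) or 2 (0.0471), and without a filter (1.31e-04), in a range up to 0.743. The deposited pathway term for oxidative phosphorylation was called among lower genes (60 of 142, adjusted p = 0.0338). UQCRC2 and COX4I1 lie on chromosome 16 and ATP5F1C on chromosome 10.

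Of 71 tested cytosolic ribosomal protein genes, 35 rose, 7 fell and 29 did not pass, against 35 and 8 adjusted over the list alone. RPL13 rose by 0.57, RPL13A by 0.51, and RPL3 and RPS15A by 0.50 each, although reads shared with processed pseudogenes make single values uncertain. The median was 0.11 (adjusted p = 0.0277 preset, and adjusted p = 0.743 with an estimated correlation). The call was lost without mutant replicate 2 (median 0.07, adjusted p = 0.197). It was also lost without the genes of chromosomes 10, 16, 20 and 22 (adjusted p = 0.105), where the median, 0.09, was little changed. Nor did fry call the list (adjusted p = 0.0951), in a range of 1.24e-05 to 0.743 over the alternatives. Glycolytic genes were not called as a list (median -0.11, adjusted p = 0.177), with 4 of 18 rising and 9 falling, as also adjusted over the list alone. PGAM1 (-0.54) and HK1 (-0.47), both on chromosome 10, had the smallest adjusted p, followed by ENO1 (-0.32) and GPI (-0.27). Without the genes of chromosomes 10, 16, 20 and 22 the glycolytic median was 0.01.

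Mitotic genes were lower in the mutant, and genes of DNA replication went both ways. Of 29 tested mitotic genes, 1 rose, 19 fell and 9 did not pass, with the same counts when adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, fell from 105 ± 3.86 to 61.1 ± 1.86 FPKM (SD, n = 3; log2 fold change -0.82), cyclin B1 (CCNB1) by 0.62, KIF11 by 0.53 and KIF20A by 0.51. The median was -0.21 (adjusted p = 2.54e-05 preset, and adjusted p = 0.366 with an estimated correlation). Among 31 replication genes, 10 rose and 8 fell, also adjusted over the list alone, with cyclin D2 (CCND2) up by 1.10 and PCNA changing by -0.60, MCM5 by -0.46 and CDT1 by 0.45. That list had a median of -0.01 and a mean of 0.04, its test pointed up (adjusted p = 0.912), and its median was above 0 under 3 of 4 other scalings. KIF11 lies on chromosome 10, CDT1 on 16, PCNA on 20 and MCM5 on 22, and each changed in the direction of its chromosome, as described below.

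Targets of p53, the apoptosis machinery, double-strand break repair and histones were not called as lists. Of 23 p53 targets, 10 rose and 5 fell (median 0.10, adjusted p = 0.333), with SESN2 (0.77), TIGAR (-0.64), MDM2 (-0.42) and CCNG1 (0.38) showing the smallest adjusted p. Of 22 BCL2 family and caspase genes, 4 rose and 9 fell (median -0.09, adjusted p = 0.543), among them BCL2L2 (0.65), PMAIP1 (0.54) and BAK1 (-0.41). Of 35 repair genes, 16 rose and 8 fell (median 0.07, adjusted p = 0.654), including DCLRE1C (-0.75), FANCA (0.67) and XRCC6 (-0.47). DCLRE1C, FANCA and XRCC6 lie on chromosomes 10, 16 and 22, in that order, and each changed in the direction of its chromosome, as described below. Of 9 histone genes, 4 rose and 2 fell (median 0.27, adjusted p = 0.0516 in the main test), with H1-4 (3.00) and H1-2 (0.82) next to H2BC21. The histone list passed in 8 of 18 alternatives, in a range of 8.20e-04 to 0.406: without mutant replicate 3 (adjusted p = 0.0365), without wild-type replicate 1, 2 or 3 (0.0175, 0.0471 and 0.0422), and with a mean FPKM of at least 5 (0.00710), among others. Its median was 0.69 without wild-type replicate 3 and 0.05 with quantile normalization. The 4 pairs of counts were the same when adjusted over the list alone. Poly(A) selection recovers most replication-dependent histone transcripts poorly.

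In the G protein and cAMP pathway, which links adenosine receptors to protein kinase A, 35 genes were tested, of which 16 rose, 8 fell and 11 did not pass, against 17 and 8 adjusted over the list alone. GNAO1, the Go alpha subunit gene, rose from 0.580 to 2.62 FPKM (log2 fold change 2.13, SE 0.12), the gamma subunit genes GNG2 and GNG4 by 1.43 and 1.02, and the protein kinase A regulatory subunit gene PRKAR2B by 0.78. The median was 0.11 (adjusted p = 0.0211 preset, and adjusted p = 0.366 with an estimated correlation). The call was lost without the genes of chromosomes 10, 16, 20 and 22 (adjusted p = 0.0978), although the median there, 0.10, was little changed. It was also lost in limma on log2(FPKM + 1) (adjusted p = 0.101), with pseudocounts of 0.1 and 0.5, with quantile normalization (0.114) and with a mean FPKM of at least 5 (0.0522). The list passed in 11 of 18 alternatives, in a range of 9.75e-05 to 0.366, with medians of 0.08 to 0.22. The adenosine list held the receptor gene ADORA2B beside genes of adenosine production, uptake and breakdown. Of its 14 tested genes, 5 rose, 3 fell and 6, ADORA2B among them, did not pass, as also adjusted over the list alone. NT5C1A rose by 0.74, ADA by 0.52 and PNP by 0.35, NT5C2 changed by -0.65, and the list was not called (median 0.10, adjusted p = 0.654). Around the edited position on 1q32.1, 6 of 12 tested genes rose and 4 fell, as also adjusted over the list alone (median 0.12, adjusted p = 0.456). They were led by ATP2B4 (0.61), SOX13 (0.58), UBE2T (0.42) and KLHL12 (0.39).

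Other signalling lists held changes in both directions and were not called. Of 30 MAPK cascade genes 8 rose and 14 fell, against 9 and 14 adjusted over the list alone (median -0.13, adjusted p = 0.367), with RPS6KA2 (0.87), MAPK3 (0.48) and MAP2K4 (-0.48) as examples. Of 27 PI3K, AKT and mTOR genes 11 rose and 6 fell (median 0.06, adjusted p = 0.143), among them EIF4EBP1 (0.91), INSR (0.90) and IRS4 (0.42). Of 24 WNT genes 10 rose and 7 fell (median 0.11, adjusted p = 0.358), including FZD2 (0.83), FZD4 (0.74) and TCF7L2 (-0.68). Of 23 TGF-beta and BMP genes 8 rose and 9 fell (median -0.01, adjusted p = 0.912, with a median above 0 under 2 of 4 other scalings), including BAMBI (-1.29), LTBP1 (0.75) and TGFB1 (0.71). For these last 3 lists the counts were the same when adjusted over the list alone.

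Antioxidant, lipid, immune and renal lists were not called either. Of 25 NRF2 targets and antioxidant genes 4 rose and 10 fell (median -0.06, adjusted p = 0.350), with HMOX1 (-1.18), GCLM (-0.87) and PRDX3 (-0.48) beside SLC7A11, and the median was 0.01 on the TPM scale. Of 23 cholesterol genes 4 rose and 13 fell (median -0.16, adjusted p = 0.220), with INSIG1 at 0.47 and SQLE at -0.30. Of 9 tested interferon-stimulated genes 4 rose and 1 fell (median 0.34, adjusted p = 0.255), among them IFI6 (1.13) and IFIT1 (0.65), and the median was -0.11 with a mean FPKM of at least 5. Of 5 tested NF-kB and inflammation genes, PTGS2 rose by 1.28, and NFKB1 (-0.38) and NFKBIA (-0.42) fell (adjusted p = 0.877). The NF-kB list had a median of -0.00, a mean of 0.12 and a test pointing down. For these 4 lists the counts adjusted over the list alone were the same. Of 9 tested renal and epithelial markers 3 rose and 5 fell, against 4 and 5 adjusted over the list alone (adjusted p = 0.654), with CDH1 (2.35), VIM (-0.84), SIX2 (-0.49) and EYA1 (0.39). Their median was -0.26 and their mean 0.12, the test pointed down, and the median was 0.22 without a filter. Apart from the nuclear respiratory chain and histone lists, the lists not called in the main test passed in at most 3 of their alternatives. With an estimated correlation, 0 of the 30 lists were called, against 12 with the preset correlation and 22 by fry, which asks whether the genes of a list move one way without setting them against other genes.

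**Figure D2:**
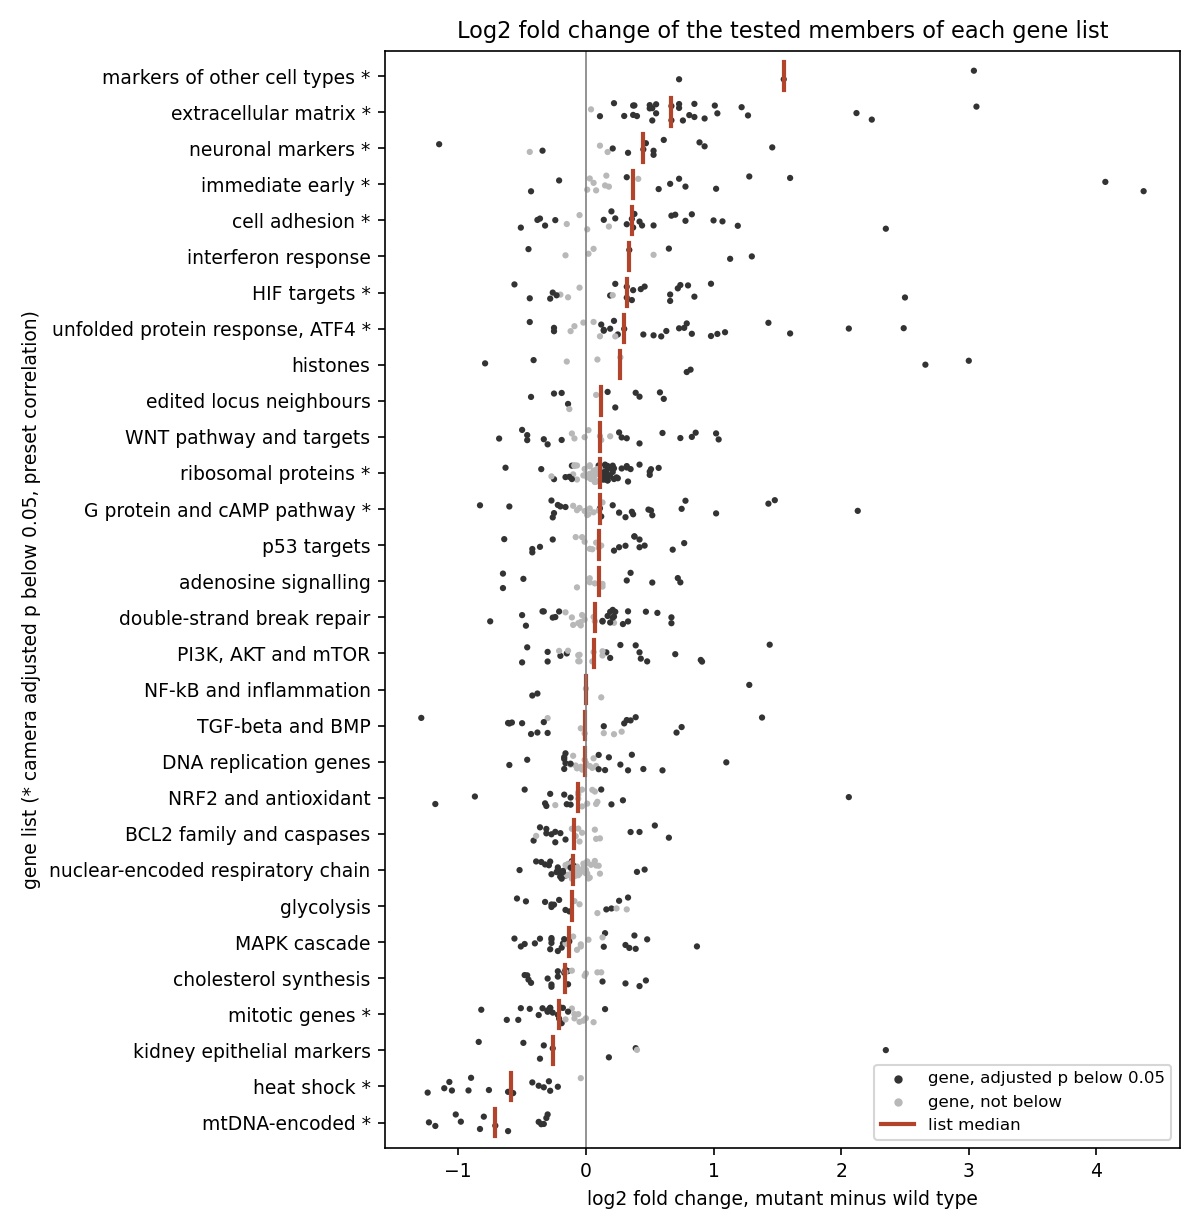
Log2 fold change (mutant minus wild type, x axis) of each tested member of the 30 gene lists (y axis), dark where its adjusted p was below 0.05 and grey where not, with red bars for the list median and a star for the 12 lists called by camera with the preset correlation. The extracellular matrix median lay at 0.67, and the heat shock and mitochondrial DNA medians lay at -0.59 and -0.71.

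Functional terms deposited with the table placed higher genes at the cell surface and in the matrix, and lower genes in the nucleus, the nucleolus and the proteasome. Over 5738 tests of terms and directions, 206 were called by one-sided Fisher tests. These tests treat genes as independent draws, and the terms were not tested with a correlation between genes. In the fixed lists the estimated correlation ran from -0.090 (histones) to 0.884 (mitochondrial DNA genes). Where the genes of a term are correlated, its adjusted p may be too small. Among genes higher in the mutant, 29 of 29 genes of the term extracellular matrix structural constituent were found where 8.61 would be drawn by chance (adjusted p = 1.17e-13). The same held for 45 of 57 genes of cell adhesion molecules (17.2 by chance, adjusted p = 9.32e-12), 38 of 57 genes with G protein-coupled receptor activity (16.9 by chance, adjusted p = 1.03e-06) and 42 of 75 genes of the cellular response to hypoxia (22.2 by chance, adjusted p = 3.34e-04). Among lower genes, 97 of 170 spliceosome genes (50.2 by chance, adjusted p = 1.16e-11), 83 of 140 genes of rRNA processing (43.1 by chance, adjusted p = 1.90e-09) and 34 of 44 proteasome genes (adjusted p = 1.13e-08) were found. Cell division (145 of 350, 108 by chance, adjusted p = 0.00288) was also among the lower terms. When only genes with at least a 2-fold difference were counted, 71 terms were called, and among genes with a mean FPKM of at least 5 there were 69.

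Genes of chromosomes 10, 16, 20 and 22 shifted together. On chromosome 10, 320 of 492 tested genes fell and 44 rose, with a median log2 fold change of -0.36, or 0.777-fold (camera adjusted p = 7.22e-19 preset, and adjusted p = 5.74e-04 with an estimated correlation). Chromosome 16 moved the other way, with 362 of 578 genes higher and 33 lower and a median of 0.29, or 1.22-fold (adjusted p = 2.95e-15 preset, and 0.0181 with an estimated correlation). Both shifts ran along the whole chromosome. All 19 complete windows of 25 neighbouring tested genes on chromosome 10 had medians of -0.45 to -0.19, and all 23 on chromosome 16 had medians of 0.09 to 0.49. On chromosome 20 (median -0.13, adjusted p = 0.00467 preset, and 0.0181 with an estimated correlation), the largest shift lay at the start of the short arm. Its first 3 windows, with gene starts from 270863 to 17969018, had medians of -0.50, -0.52 and -0.56, and the next had 0.13. Of the other windows, those from 23.6 to 32.8 Mb (-0.16) and from 45.9 to 49.9 Mb (-0.26) were also below -0.15. The chromosome 22 median was -0.16 (adjusted p = 7.66e-04 preset), with 6 windows below -0.15, of which 4 lay from 40.3 to 50.5 Mb (-0.33 to -0.22) and the others at 19.4 to 20.9 Mb (-0.22) and 31.6 to 37.1 Mb (-0.24), but adjusted p = 0.226 with an estimated correlation. The other 18 autosomes and the X chromosome were not called, and their medians lay between -0.05 and 0.06. In the 424 complete windows outside chromosomes 10, 16, 20 and 22, 5 medians exceeded 0.3 in size, and the lowest, -0.70, held the HOXA cluster on chromosome 7. Without the genes of these 4 chromosomes, an alternative added after seeing the data, 6096 of 10818 genes were called. Genes named above that changed in the direction of their chromosome include INA, NT5C2, TCF7L2, BAMBI and PRDX3 on chromosome 10. HERPUD1, RPL13, RPS15A and MAPK3 on chromosome 16 and HMOX1 on chromosome 22 did so too. DDIT4 and IFIT1 on chromosome 10, ADA on chromosome 20 and RPL3 on chromosome 22 went the other way. The genes that shared the direction all changed by more than the median of their chromosome. The excess was largest for HERPUD1 (1.43), HMOX1 (-1.18), BAMBI (-1.29) and INA (-1.15).

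**Figure D3:**
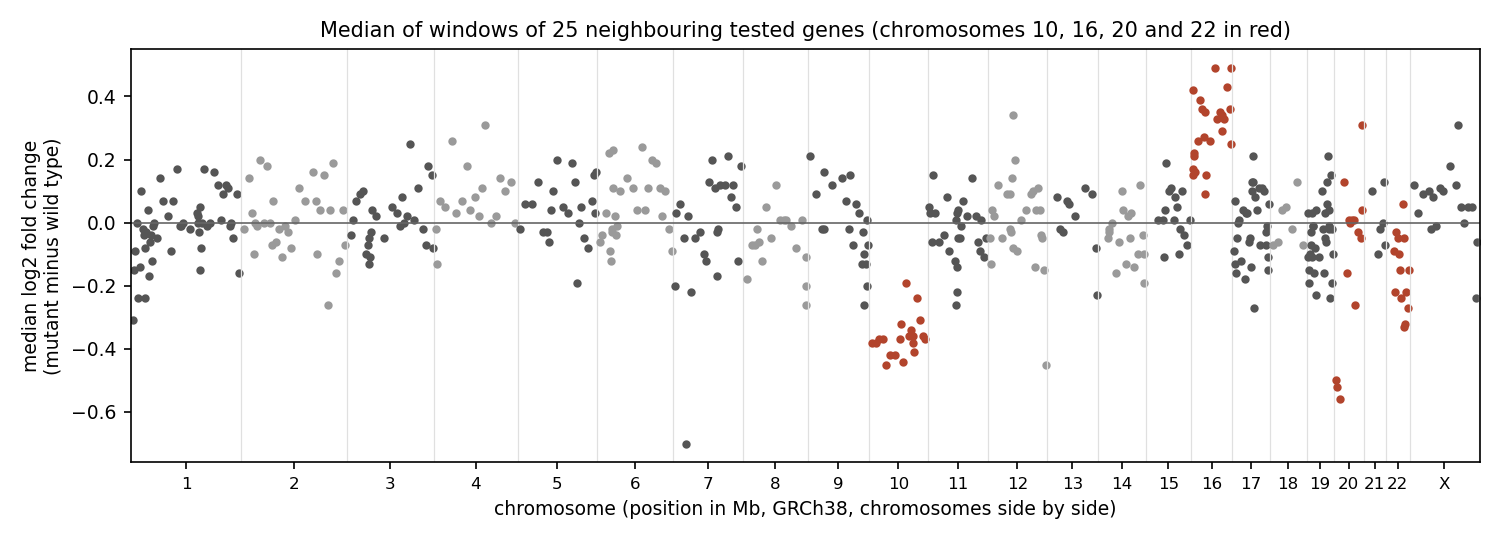
Median log2 fold change (mutant minus wild type, y axis) in windows of 25 neighbouring tested genes along chromosomes 1 to 22 and X (x axis, Mb on GRCh38), with chromosomes 10, 16, 20 and 22 in red; the last window of a chromosome can hold fewer genes. Windows lay at -0.45 to -0.19 over chromosome 10, mostly at 0.09 to 0.49 over chromosome 16, and at -0.50 to -0.56 at the start of chromosome 20.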

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

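Most results kept their direction and their side of the threshold, and no called list, chromosome or named gene changed direction. The balance of called genes turned with quantile normalization (3277 higher, 3608 lower). Of all genes called in the main test, 1 was called with the opposite sign with quantile normalization. Medians of lists that were not called did change sign: replication, TGF-beta, NRF2 and NF-kB genes under other scalings, glycolysis without genes of 4 chromosomes (0.01), interferon genes with a mean FPKM of at least 5 (-0.11) and renal markers without a filter (0.22). Library totals as the scaling, terms with libraries left out, and tests without genes of chromosomes 10, 16, 20 and 22 were chosen after seeing the data. With 1 library left out in turn, 6437 to 7407 genes were called, 494 to 642 by at least 2-fold, with 12 to 14 lists, 157 to 215 terms and 4 chromosomes, and ADORA1 ran from 0.09 to 0.35. DESeq2 called 6723 genes, and without genes of chromosomes 10, 16, 20 and 22 there were 6096, with 10 lists and 178 terms. The number of genes with at least a 2-fold difference depended most on the method. It was 166 (115 higher, 51 lower) with quantile normalization, 193 (154, 39) in limma on log2(FPKM + 1), 330 (274, 56) with a pseudocount of 0.5, 190 (153, 37) without trend, 187 (152, 35) with robust limma and 202 (161, 41) with array weights. In these fits the pseudocount shrinks differences of weakly expressed genes by construction. It was 1874 (1427, 447) of 32791 genes without a filter, 1455 (1178, 277) of 16229 with filterByExpr and 1388 (1134, 254) of 18805 in DESeq2 without a filter, where more genes were tested. With a mean FPKM of at least 5, fewer genes (7304) were tested and 4597 (2300, 2297) were called, 122 (95, 27) by at least 2-fold, with 69 terms. Counting only genes with at least a 2-fold difference gave 71 terms. With an estimated correlation 0 lists were called, and with fry, which does not set a list against other genes, 22. The estimated setting differs from the preset one in its degrees of freedom as well as in the correlation. For chromosome 10 the estimated correlation was -0.002, below the preset 0.01, yet the unadjusted camera p went from 3.14e-20 to 2.49e-05. How much of the loss of list calls is due to correlation was not tested. The replicate block called 7069 genes, and the correlations of deviations between pairs of libraries ran from -0.04 to 0.04, so no pairing of replicates was seen. Depth limits weakly expressed genes such as ADORA1.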

Other observations

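HOX genes and HLA genes were looked at as groups after their members had appeared among the largest changes, and their genes were chosen after their values were seen. Of 34 tested HOX genes 0 rose and 27 fell, with a median log2 fold change of -0.64. In the HOXA cluster on chromosome 7, 9 of 10 fell (median -1.02), in HOXB on chromosome 17, 7 of 9 (-0.67), in HOXC on chromosome 12, 4 of 8 (-0.20, with single values up to 0.32), and in HOXD on chromosome 2, 7 of 7 (-0.60). No test was run on a cluster as a set. All 13 tested HLA genes rose (median 1.03). The 8 class II genes had a median of 1.42 and a range of 0.96 to 3.04, and the other 5 had a median of 0.48. Reads shared between HLA genes, and overlapping HOX transcripts, make single values uncertain.

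Of the tests that follow, those on a few strongly changed genes and on a culture or clone difference were chosen only after the result was seen. The list of retinoic acid targets was written after the fall of HOX genes was seen, but before its own values were.

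The shifts of chromosomes 10, 16 and 20 could reflect a copy-number difference between the edited and wild-type cells. A copy-number difference predicts a clear shift of the same sign at every expression level: from the lowest to the highest of 3 expression classes, the medians were 0.43, 0.29 and 0.23 on chromosome 16 and -0.46, -0.56 and -0.60 at the start of chromosome 20, which meets it. On chromosome 10 they were -0.11 (SE 0.08), -0.37 and -0.43, so its lowest class did not decide. The SE of a median is here the SD of medians over resampled genes. It treats genes as independent and does not measure the spread between libraries. The explanation stays open for all 3 blocks, since meeting the prediction does not show the cause and no DNA was analysed here. GC content or gene length did not account for the shifts, since the smallest median after removing these trends was 0.26, on chromosome 16. Nor did a few strongly changed genes, since at least 78.3% of the genes of each block lay on its side.

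For the rise of ATF4 targets and the fall of heat shock genes, the variant is the biological explanation that the design names, and it was not tested. Chromosome shifts carrying the list genes did not account for most of it. Without genes of chromosomes 10, 16, 20 and 22, in the same fit, the ATF4 median went from 0.30 to 0.25. That is 0.84 of its size, and 0.71 to 0.99 with a library left out. The heat shock median went from -0.59 to -0.57, which is 0.97 of its size (0.85 to 1.00). In a new fit without those genes the ATF4 median was 0.24. Scaling did not either, with a smallest median of 0.29 over 4 other scalings. A culture or clone difference that coincides with genotype could not be separated from the variant, since the number of label tags naming a batch, clone, passage or day was 0.

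The fall of HOX genes was not a shift of the chromosomes that carry them, since their median minus that of their own chromosome was -0.63. Lower retinoic acid signalling, possibly through ALDH1A2, stayed open: 14 tested retinoic acid targets outside the clusters had a median of -0.22 (SE 0.25 from resampled genes), with 4 rising and 8 falling. Of these, DHRS3 (-2.07) and RARB (-1.03) fell while CRABP2 (1.51) and CYP26B1 (0.84) rose, all chosen after their values were seen.

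The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave the most in each case, so 1 of 10 divisions reached its value. It gave 7284 called genes against at most 0 in the others, 546 genes of at least 2-fold against 0, and 206 terms against 0. It gave 12 gene lists against 11, and 4 chromosomes against 3, so the counts of called lists and chromosomes with the preset correlation barely separated the real division from the others. Every other division mixed libraries of both genotypes. The genotype difference therefore widened the spread within its groups and remained in part between them. The counts of the other divisions, 0 or not, are thus no measure of what chance alone would give.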
